A study of Mus musculus with 16 samples.

How the data were processed

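RNA was measured by paired-end sequencing of total RNA from 16 subcutaneous B6MyC-CaP tumours, 4 each from the Vehicle, ENZ, ADF and ADF+ENZ groups. The deposited table holds raw counts per gene and library, and the submitters' processing notes name Trim Galore, HISAT2, featureCounts and DESeq2, with no versions, and the genome builds mm39 and GRCh38, with no role given for each. Its values were checked to be whole numbers, so each deposited count was used as a count. The table has 55414 gene IDs and 5 further entries with the names that htseq-count writes, for reads in no feature, ambiguous reads, reads of low quality, reads not aligned and reads aligned to several places. These 5 were kept out of the tests and used as measures of each library. Symbols were found for 52081 IDs in a mouse annotation of an earlier build than mm39, which was used for names, gene class, GC content, length, span and the order of neighbours. IDs without a symbol held 3.51% of gene counts.

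Counts assigned to genes ran from 10072489 to 25505655 per library. A floor of 3 counts over a group was used where a gene had no count, and such floors cover counting error only. Between replicates of a group, the chi-square per degree of freedom over the 24 pairs was 5.19 to 33.9, above counting error.

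Genes were tested in edgeR 4.0.16 (R 4.3.3) by robust quasi-likelihood on all 16 libraries in one fit, with TMM normalization and filterByExpr at a minimum count of 10 and a total of 15, which left 18946 genes. There were 5 pairwise comparisons and 3 other contrasts: the average fasting effect, the average enzalutamide effect and their interaction. Each contrast was adjusted by Benjamini-Hochberg on its own, and a gene passed at an adjusted p under 0.05. CPM are TMM-scaled, and log2 CPM used a prior count of 2. Comparisons with Vehicle share its 4 libraries. Library measures and marker levels were compared with exact two-sided permutation tests over 70 assignments, adjusted by Benjamini-Hochberg. The 65 tests of library measures were adjusted together. The 80 tests of markers were adjusted over the 16 lists within each comparison.

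Before the data were examined, 39 gene lists with 964 genes were fixed from general knowledge: 16 for cell types, 21 for pathways and 2 for sample quality. The comparisons, the main test and the settings to vary were fixed at the same point. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which does not compare a list with other genes. Named genes followed a rule of the same date: the 10 largest changes in each direction among genes past the threshold with a mean of at least 1 CPM and groups that did not overlap, up to 4 members per list, the 5 interaction genes with the smallest p, and a few genes chosen in advance, of which Fkbp5, Tmprss2, Pbsn and Myc are given. Some genes that the rule names are not reported here. Genes of the Mdm2 region and a few list members were added after their values were seen.

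The settings chosen then were DESeq2 size factors within edgeR, DESeq2 1.42.0, limma-voom with quality weights, no filter (37369 genes), a stricter filter of at least 1 CPM in 4 libraries (17042 genes), a skeletal muscle covariate, only the 2 groups compared, and leaving out each library in turn. Chosen after the data were seen were protein-coding genes alone, removal of trends on GC content and length (18800 genes), and the percent of reads in no feature as a covariate. Other splits of the libraries were counted, 35 for each pairwise comparison and 100 drawn for each other contrast. Principal components used the 1000 most variable genes.

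The pipeline was tested on simulated data with changes planted in 200 genes. In ENZ against Vehicle it recovered 60% of genes planted at 2-fold and 92% at 4-fold, in ADF against Vehicle 42% and 94%, and in ADF+ENZ against ENZ 64% and 86%. For the interaction it recovered 36% and 78%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Fasting state at collection, sequencing batch and sequencing date were not used here.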

Results

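The data collected were RNA-seq gene counts from 16 tumours of B6MyC-CaP cells, a prostate cancer cell line made from the Hi-MYC transgenic mouse on a C57BL/6 background. The tumours grew under the skin of male C57BL/6 mice that were 6 weeks old at implantation. There were 4 groups of 4 tumours. Vehicle mice ate freely. ENZ mice received 20 mg/kg of enzalutamide, an antiandrogen drug, by gavage each day. ADF mice were on alternate-day fasting, with 24 h without food followed by 24 h with it, and ADF+ENZ mice received both treatments. Whether a tumour was taken on a fasting or a feeding day is not given in the sources used here. The labels number each tumour but do not state that each came from its own mouse, so all p-values measure the spread between these samples. The series title is about translation, which transcript counts do not measure.

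Counts assigned to genes ranged from 15722655 to 18313259 per library in Vehicle, from 10630096 to 23558532 in ENZ, from 12289755 to 16140246 in ADF and from 10072489 to 25505655 in ADF+ENZ. Libraries of the ADF group differed from those of Vehicle in make-up. Reads in no annotated feature were 32.9% ± 2.73 (SD, n = 4) of all reads in ADF, against 25.9% ± 2.25 in Vehicle, 25.9% ± 1.45 in ENZ and 24.0% ± 2.05 in ADF+ENZ. Reads aligned to several places were 4.695% ± 0.414 in ADF, 7.44% ± 0.294 in Vehicle, 7.89% ± 0.0666 in ENZ and 7.09% ± 0.591 in ADF+ENZ (SD, n = 4). Both differences between ADF and Vehicle gave p = 0.0286 in an exact two-sided permutation test, the smallest p that 70 assignments allow. Of the 65 tests of library measures 15 gave this p, and after Benjamini-Hochberg adjustment 0 passed (smallest adjusted p = 0.124). With so high a floor of p, passing over 65 tests was hardly possible, so this does not show that the libraries were alike. The same unadjusted p was reached for reads outside features and for reads aligned to several places between ADF+ENZ and ADF. These facts stand beside each comparison that uses the ADF libraries. The first principal component of the 1000 most variable genes held 27.4% of their variance, and ADF+ENZ replicate 3 had the highest score on it, 39.7, with the other 15 libraries between -22.1 and 17.6.

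**Figure D1:**
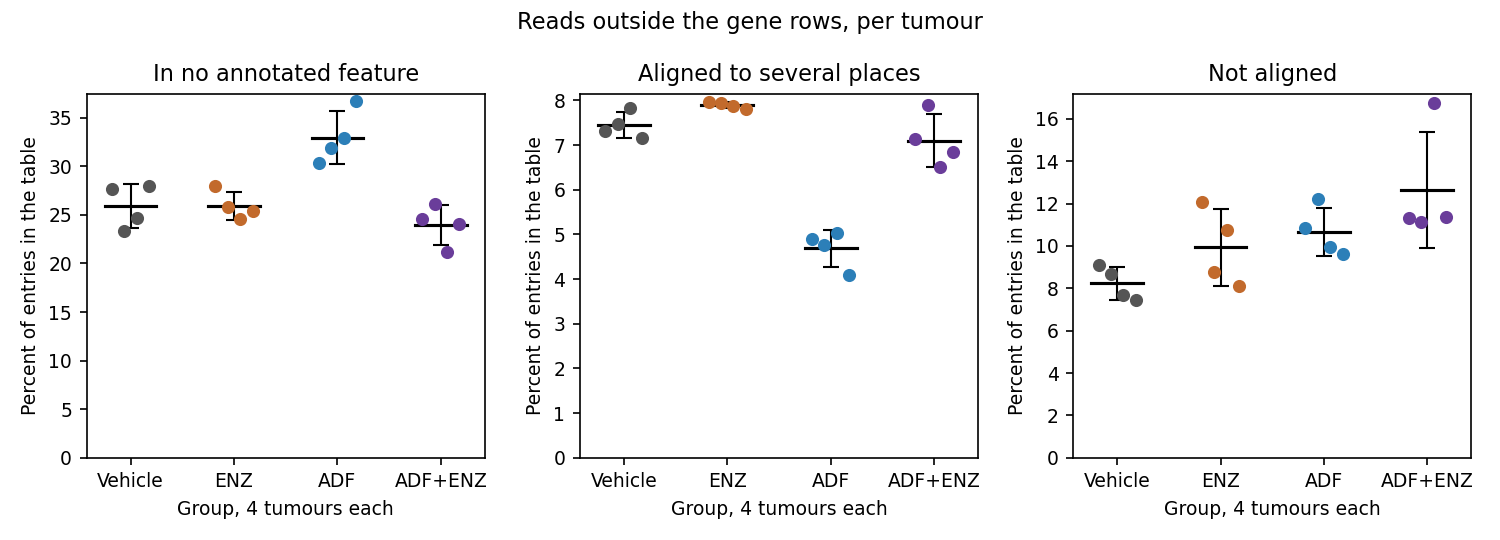
Percent of reads in no annotated feature, aligned to several places and not aligned in each of the 16 libraries (points), with the mean and SD of each group. The 4 ADF libraries lie between 30.3% and 36.7% for reads outside features, above the 12 other libraries, and between 4.10% and 5.03% for reads aligned to several places, below the others.

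Mouse Myc shares its name with the oncogene of the transgene. Its level was 96.1 ± 7.04 CPM (counts scaled by library size) in Vehicle, 103.8 ± 18.04 in ENZ, 117.4 ± 25.6 in ADF and 124.3 ± 18.6 in ADF+ENZ (SD, n = 4), with no comparison past the threshold (edgeR's smallest adjusted p = 0.106). These are counts of the mouse gene, and whether the transgene's own transcript changed was not measured.

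The androgen-dependent genes Pbsn and Tmprss2 were below or close to detection. Probasin (Pbsn) had 0 counts in all groups. A count of 0 allows up to 0.0436 CPM over the Vehicle libraries, 0.0460 over ENZ, 0.0557 over ADF and 0.0469 over ADF+ENZ, from 3 counts per group. Tmprss2, an androgen-induced protease gene, had 21, 14, 13 and 12 counts in Vehicle, ENZ, ADF and ADF+ENZ. Differences in these 2 genes were not detectable at this depth.

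Fkbp5, a cochaperone gene induced by androgen and by glucocorticoid, changed in several comparisons. Its level was 400.3 ± 63.4 CPM in Vehicle, 170.3 ± 26.6 in ENZ, 241.8 ± 69.5 in ADF and 355.1 ± 85.4 in ADF+ENZ (SD, n = 4). It fell in ENZ by 1.23 on the log2 scale (SE 0.202, edgeR adjusted p = 0.00240) and in ADF by 0.73 (SE 0.1995, 0.0346). In ADF+ENZ it was -0.17 against Vehicle (SE 0.198, edgeR adjusted p = 0.609), and it was 1.06 higher than in ENZ (SE 0.201, 0.0240). Against ADF it was 0.55 and did not pass (edgeR adjusted p = 0.0678), but it passed by DESeq2 (0.57) and limma-voom (0.61), and without ADF replicate 1 (0.77) or ADF+ENZ replicate 4 (0.66). The interaction, the fasting effect with enzalutamide minus the fasting effect without it, was 1.79 (SE 0.283, edgeR adjusted p = 0.00787) and passed in each of the 16 fits with 1 library left out, from 1.64 to 2.005. The percent of reads outside features was fitted as a covariate in edgeR only. With it the interaction was 1.32 (SE 0.424) and did not pass (edgeR adjusted p = 0.874). Nor did ADF against Vehicle pass with it (-0.37, SE 0.312, edgeR adjusted p = 0.742). Without the covariate DESeq2 gave adjusted p = 8.89e-08 for the interaction and 0.00291 for ADF against Vehicle. The ADF call was lost without Vehicle replicates 2 (-0.70), 3 (-0.68) or 4 (-0.69) or ADF replicates 2 (-0.63), 3 (-0.66) or 4 (-0.70), and with no filter (-0.76). The ADF+ENZ against ENZ call was lost without ENZ replicates 2 (1.02), 3 (0.98) or 4 (1.09) or ADF+ENZ replicates 1 (0.995) or 3 (0.91), with no filter (1.04) and with the covariate (0.94).

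**Figure D2:**
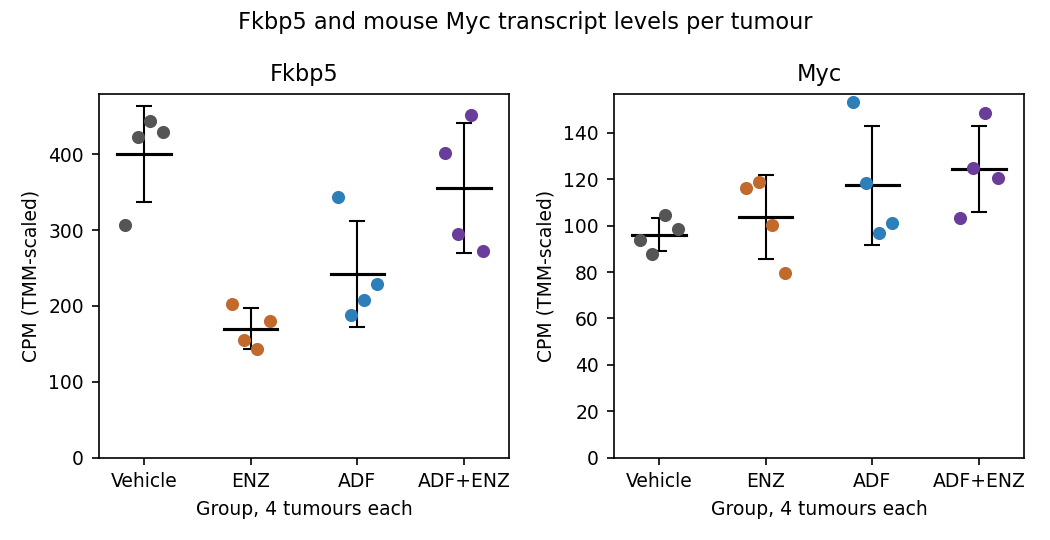
CPM of Fkbp5 and Myc in each tumour of the 4 groups (points), with the mean and SD of each group. Fkbp5 is lower in ENZ (170.3) than in Vehicle (400.3) and ADF+ENZ (355.1), while the group means of Myc lie between 96.1 and 124.3.

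ENZ against Vehicle asks what enzalutamide changed in tumours of mice that ate freely. The largest losses were in genes of varied function. Lbp, which encodes the lipopolysaccharide-binding protein, fell from 173.5 ± 73.4 to 18.2 ± 3.99 CPM (SD, n = 4; log2 -3.27, SE 0.454, edgeR adjusted p = 0.00139). Nr1h4, the bile acid receptor gene, fell from 15.1 ± 0.154 to 1.82 ± 0.972 CPM (log2 -3.12, SE 0.274, edgeR adjusted p = 2.37e-06). Adgrg2, an adhesion receptor gene, fell from 114.2 ± 29.6 to 16.7 ± 3.48 CPM (log2 -2.78, SE 0.219, edgeR adjusted p = 3.66e-06), and the interleukin-18 receptor gene Il18r1 from 49.5 ± 8.46 to 7.41 ± 2.10 CPM (log2 -2.76, SE 0.272, 5.08e-05). Other losses were Serpina3m (log2 -3.87), a protease inhibitor gene in a cluster of close paralogs whose reads can be shared, and Thsd7a (-3.09). Genes that rose included Capn6, of the calpain family, from 5.66 ± 1.36 to 23.7 ± 8.22 CPM (log2 2.07, SE 0.286, edgeR adjusted p = 0.000613), Insyn1 (log2 1.80), Ptn, the pleiotrophin gene (2.09), and Dmp1 (2.29).

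Members of the androgen response list moved both ways in ENZ against Vehicle. Of 90 tested members, 2 rose, 9 fell and 79 did not pass; adjusted over the list alone, 3 rose and 17 fell. Fkbp5 fell, as did the hypoxia- and androgen-induced Ndrg1 (log2 -1.03), the scaffold gene Pdlim5 (-0.51) and the keratin gene Krt19 (-3.71, from 2.49 to 0.195 CPM). Pmepa1, an androgen-induced gene whose product restrains TGF-beta signalling, rose from 400.3 ± 76.7 to 829.9 ± 86.8 CPM (log2 1.05, SE 0.150, edgeR adjusted p = 0.000441). The transcript annotated opposite to it, Pmepa1os, rose by 2.28; the strand setting of the counting is not given in the sources used here, so reads of the pair may be shared. For the list, camera gave an adjusted p = 0.0198 downward, and adjusted p = 0.569 with an estimated correlation. That call was lost without Vehicle replicate 2 (adjusted p = 0.110) or ENZ replicate 1 (0.157), and with GC and length trends removed. In the prostate secretory list, 2 of 6 tested members fell, Fkbp5 and the claudin gene Cldn10 (log2 -2.36), with a camera adjusted p = 0.0103, and adjusted p = 0.471 with an estimated correlation.

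Glucocorticoid-induced genes were lower in ENZ: 5 of 19 tested members fell and none rose, and 7 fell adjusted over the list alone. Zbtb16, a transcription factor gene, fell from 93.8 ± 10.1 to 15.2 ± 6.05 CPM (log2 -2.63, SE 0.393, edgeR adjusted p = 0.00223), the iron-scavenging lipocalin gene Lcn2 by 2.39 and the metallothionein gene Mt1 by 0.77. The list's median log2 change was -0.48 (camera adjusted p = 1.2e-06; adjusted p = 0.471 with an estimated correlation). In the glycolysis and hypoxia list 17 of 31 members fell, and 21 adjusted over the list alone, with a median of -0.58 (camera adjusted p = 1.12e-15; adjusted p = 0.471 with an estimated correlation). Ero1l, an oxidase of the endoplasmic reticulum, fell from 118.4 ± 29.8 to 40.2 ± 8.71 CPM (log2 -1.56, SE 0.183, edgeR adjusted p = 0.000163), Egln3, a HIF prolyl hydroxylase gene, by 1.01 and P4ha2, a collagen prolyl hydroxylase gene, by 0.93. The number that fell was 7 without Vehicle replicate 3, 7 without ENZ replicate 3 and 8 without ENZ replicate 4.

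Interferon response genes were also lower, with 4 of 38 down (5 adjusted over the list alone) and a median of -0.29. Isg20, an exonuclease gene, fell by 0.996 and the transcription factor gene Stat2 by 0.63 (camera adjusted p = 1.87e-06; adjusted p = 0.569 with an estimated correlation). Of 17 antigen presentation genes 1 fell, Tapbp (log2 -0.79), and 2 adjusted over the list alone (camera adjusted p = 0.000305; adjusted p = 0.576 with an estimated correlation). Of 38 ATF4 and amino acid response genes 4 fell, 6 adjusted over the list alone, among them Nupr1 (-0.74) (camera adjusted p = 0.000165; adjusted p = 0.569 with an estimated correlation). S phase genes had a median of 0.27, with 3 of 36 up and 9 adjusted over the list alone (camera adjusted p = 1.95e-06; adjusted p = 0.569 with an estimated correlation). The 3 were Tyms (0.51), Mcm7 (0.41) and Rfc4 (0.46), each of which lost its call in at least 6 of the 8 fits with 1 library left out. MYC-induced ribosome biogenesis genes had 2 of 48 up, Dctpp1 (0.88) and Ppan (0.40), and 2 adjusted over the list alone (camera adjusted p = 1.19e-05; adjusted p = 0.569 with an estimated correlation). Autophagy and lysosome genes had 2 of 32 down, 7 adjusted over the list alone (camera adjusted p = 0.000321; adjusted p = 0.542 with an estimated correlation). Fn1, the fibronectin gene, fell from 11210 ± 2498 to 5357 ± 540 CPM (log2 -1.07). Lists share members: Fkbp5 is in the androgen, prostate secretory and glucocorticoid lists, Ndrg1 in the androgen and glycolysis lists, and Krt19 in the androgen and luminal lists.

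In total 1028 of 18946 genes changed in ENZ against Vehicle, 342 up and 686 down, with 254 of them by more than 2-fold. The CPM ranges of the 2 groups did not overlap for 2271 genes, 11.99%, where chance gives 2.86%, and for 893 of the changed genes. The count was 461 without Vehicle replicate 3, 634 without ENZ replicate 2, 403 without ENZ replicate 3 and 613 without ENZ replicate 4. It was 1577 by DESeq2 and 1655 by limma-voom. Of the 74 named genes that passed, 37 kept their call in every fit with 1 library left out.

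ADF against Vehicle asks what alternate-day fasting changed in tumours without enzalutamide, in libraries that differ in reads outside features (32.9% in ADF, 25.9% in Vehicle). Genes of glucose breakdown and of the hypoxia response were lower. Ldha, lactate dehydrogenase A, fell from 663.5 ± 114.7 to 333.7 ± 43.4 CPM (SD, n = 4; log2 -0.99, SE 0.123, edgeR adjusted p = 0.000207) and Tpi1, triosephosphate isomerase, from 515.4 ± 118.8 to 243.0 ± 18.5 CPM (SE 0.135, 0.000207). Vegfa, the main angiogenic growth factor gene, fell from 308.0 ± 55.3 to 166.2 ± 11.9 CPM (log2 -0.89, SE 0.114, edgeR adjusted p = 0.000263). Its relative Pgf fell from 72.9 ± 7.99 to 20.5 ± 8.07 CPM (log2 -1.83, SE 0.271, edgeR adjusted p = 0.00173) and the aldolase gene Aldoc from 4.10 ± 1.12 to 0.759 ± 0.390 CPM (log2 -2.43, SE 0.315, 0.000272). In the list, 24 of 31 members fell, 27 adjusted over the list alone, and the median was -0.99 (camera adjusted p = 6.2e-24; adjusted p = 0.191 with an estimated correlation).

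Protein folding, lysosomal and nuclear-encoded oxidative phosphorylation genes were lower in the same ADF libraries. Of 24 genes of ER chaperones and the unfolded protein response 11 fell, 15 adjusted over the list alone, among them calreticulin, Calr (log2 -0.55, SE 0.0997, edgeR adjusted p = 0.00315), Pdia4 (-0.54), Herpud1 (-0.46) and Hsp90b1 (-0.46); camera gave an adjusted p = 7.79e-07, and adjusted p = 0.366 with an estimated correlation. Of 16 heat shock genes 7 fell, 9 adjusted over the list alone, with Hspb1 from 153.3 ± 62.8 to 53.9 ± 5.35 CPM (log2 -1.51; camera adjusted p = 7.79e-07; adjusted p = 0.191 with an estimated correlation). Of 32 autophagy and lysosome genes 13 fell and 1 rose, 19 and 1 adjusted over the list alone. They included the lysosomal hexosaminidase gene Hexa (log2 -0.64, SE 0.0859, edgeR adjusted p = 0.000338), the proton pump gene Atp6v1a (-0.45), the mitophagy receptor gene Bnip3l (-0.55) and Gabarap (-0.42); camera gave an adjusted p = 8.43e-08, and adjusted p = 0.191 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 11 of 60 down, 25 adjusted over the list alone, such as Cox6b1 (-0.41) and Uqcrc2 (-0.38) (camera adjusted p = 6.72e-08; adjusted p = 0.516 with an estimated correlation). None of the 15 mitochondrially encoded transcripts passed, and camera did not call them (adjusted p = 0.0842), although it did, downward, with GC and length trends removed and in 2 of the 8 fits with 1 library left out. Of 22 immediate early genes 2 fell, 6 adjusted over the list alone (camera adjusted p = 0.0433; adjusted p = 0.666 with an estimated correlation), a call lost without Vehicle replicates 1, 2 or 3 or ADF replicate 4, and with GC and length trends removed.

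Cholesterol synthesis and amino acid response genes were lower in ADF as well. In cholesterol synthesis 7 of 24 genes fell, and adjusted over the list alone 16 fell and 1 rose, with a median of -0.59 (camera adjusted p = 8.43e-08; adjusted p = 0.450 with an estimated correlation). Sc5d, a late enzyme of the pathway, fell by 0.75 on the log2 scale, and Scd2, a fatty acid desaturase gene, was 1 of 2 genes down among the 17 of the fatty acid synthesis list, at -0.66; camera did not call that list (adjusted p = 0.371). Of 38 ATF4 and amino acid response genes 8 fell and 1 rose, 16 and 1 adjusted over the list alone (camera adjusted p = 1.46e-07; adjusted p = 0.366 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, fell from 38.3 ± 1.80 to 21.6 ± 1.84 CPM (log2 -0.83, SE 0.123, edgeR adjusted p = 0.000768) and the transcription factor gene Atf5 by 0.69. Of 42 translation factors 7 fell, 9 adjusted over the list alone, with Eif1ax at -0.36 (camera adjusted p = 0.000128; adjusted p = 0.666 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 2 fell, the same number adjusted over the list alone, with a median of -0.20 (camera adjusted p = 1.22e-07; adjusted p = 0.682 with an estimated correlation). Cpt1a, the entry step of fatty acid oxidation, rose from 206.2 ± 33.7 to 289.4 ± 16.9 CPM (log2 0.49, SE 0.118, edgeR adjusted p = 0.0165), a call that was lost without Vehicle replicate 2. The other 19 genes of its list did not pass, and camera did not call it (adjusted p = 0.977).

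Androgen response genes had 13 of 90 down and 3 up in ADF, 16 and 5 adjusted over the list alone, among them Ndrg1 (log2 -1.01) and Acsl3 (-0.97), an acyl-CoA synthetase gene (camera adjusted p = 0.00936; adjusted p = 0.366 with an estimated correlation). Glucocorticoid-induced genes had 4 of 19 down and 1 up, 7 and 2 adjusted over the list alone, with Mt1 at -0.98 and Lcn2 at -2.66 (camera adjusted p = 0.00806; adjusted p = 0.666 with an estimated correlation). Antigen presentation genes had 3 of 17 down, the same number adjusted over the list alone (camera adjusted p = 0.000144; adjusted p = 0.682 with an estimated correlation). Of 16 circadian clock genes 2 fell, Nfil3 by 1.20 and Bhlhe40 by 0.71, with 4 down and 1 up adjusted over the list alone; camera did not call the list (adjusted p = 0.0877). Genes that rose included Clca3a1 (2.31), Psapl1 (2.19), the kinase gene Nek10 (2.01), Fpr1 (1.89), a formyl peptide receptor gene, Syt15 (1.80) and the calcium pump gene Atp2b3 (1.76).

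The classes of genes differed in direction. Of 13766 protein-coding genes 397 rose and 843 fell in ADF against Vehicle, while 158 of 2064 long noncoding genes rose and 12 fell. Of 1199 genes of the provisional TEC class of the annotation, 155 rose and 3 fell, with a median log2 change of 0.42. In total 1707 of 18946 genes changed, 767 up and 940 down, with 406 of them by more than 2-fold. CPM ranges did not overlap for 3126 genes, 16.5%, against 2.86% by chance, and for 1498 of the changed genes. The count was 777 without Vehicle replicate 2, 713 without Vehicle replicate 3, 1055 without ADF replicate 3 and 610 without ADF replicate 4, and 41 of the 91 named genes that passed kept their call in every such fit. With the percent of reads outside features as a covariate, 6 genes passed, and with protein-coding genes alone 1119 passed.

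ADF+ENZ against Vehicle asks what the combination changed. Lrrc15, a gene known from activated stroma, rose from 7.89 ± 3.70 to 68.4 ± 52.0 CPM (SD, n = 4; log2 3.10, SE 0.621, edgeR adjusted p = 0.00774). Lbp fell from 173.5 ± 73.4 to 11.2 ± 7.42 CPM (log2 -3.89, SE 0.471, edgeR adjusted p = 0.000432). Lcn2 fell by 3.48, Cldn10 by 3.35 and the laminin gene Lamc3 by 2.99. Krt19 fell from 2.49 to 0.0204 CPM, a mean that lies under 3 counts per group. Cpt1a rose from 206.2 ± 33.7 to 324.1 ± 38.2 CPM (log2 0.65, SE 0.118, edgeR adjusted p = 0.00187). Other genes that rose were Apoc4 (2.47), Siglec15 (2.27), the microRNA gene Mir212 (2.08) and Nek10 (1.91).

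Glycolysis and hypoxia genes were again lower: 22 of 31 fell, 26 adjusted over the list alone, with a median of -0.76 (camera adjusted p = 2.31e-15; adjusted p = 0.730 with an estimated correlation). Ero1l fell from 118.4 ± 29.8 to 33.3 ± 3.63 CPM (SE 0.185, edgeR adjusted p = 2.84e-05), Egln3 by 1.30 and the pyruvate dehydrogenase kinase gene Pdk1 by 1.19. Of 38 interferon response genes 18 fell, the same number adjusted over the list alone, with a median of -0.44 (camera adjusted p = 1.27e-08; adjusted p = 0.730 with an estimated correlation). Isg20 fell from 11.7 ± 1.60 to 4.48 ± 0.800 CPM (log2 -1.38, SE 0.181, edgeR adjusted p = 0.000139), the antiviral tetherin gene Bst2 by 0.69, Stat2 by 0.68 and the RNA sensor gene Ddx58 by 0.46. Antigen presentation genes had 1 of 17 down, also 1 adjusted over the list alone (camera adjusted p = 0.000313; adjusted p = 0.779 with an estimated correlation). ATF4 and amino acid response genes had 12 of 38 down, 15 adjusted over the list alone, with Gdf15 at -0.99, Nupr1 at -0.72 and the alanine transaminase gene Gpt2 at -0.64 (camera adjusted p = 0.000562; adjusted p = 0.730 with an estimated correlation).

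MYC-induced ribosome biogenesis genes were higher in ADF+ENZ than in Vehicle. Of 48 members 15 rose and none fell; adjusted over the list alone, 26 rose and 2 fell (camera adjusted p = 3.09e-08; adjusted p = 0.730 with an estimated correlation). Tbrg4 rose by 0.64 on the log2 scale, Bop1 by 0.44 and Ppan by 0.43. Of 15 mitochondrially encoded transcripts 7 rose, 8 adjusted over the list alone, such as mt-Co3 (0.59) and mt-Atp6 (0.78) (camera adjusted p = 4.31e-05; adjusted p = 0.730 with an estimated correlation). Androgen response genes had 11 of 90 up and 7 down, 13 and 7 adjusted over the list alone; the median was 0.03 and the mean -0.09, and camera did not call the list (adjusted p = 0.786). Pmepa1 rose by 0.96. Fatty acid oxidation genes had 3 of 20 up, 4 adjusted over the list alone (Cpt1a, Eci2 at 0.54 and Slc25a20 at 0.36), and the list was not called (camera adjusted p = 0.138). In total 2369 of 18946 genes changed, 1131 up and 1238 down, with 548 by more than 2-fold. CPM ranges did not overlap for 3269 genes, 17.2%, against 2.86% by chance, and for 1976 of the changed genes. The count was 1503 without Vehicle replicate 3, 1548 without Vehicle replicate 4, 1202 without ADF+ENZ replicate 3 and 1579 with reads outside features as a covariate, and 68 of the 104 named genes that passed kept their call with any 1 library left out.

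ADF+ENZ against ENZ asks what fasting changed in tumours that received enzalutamide. Reads outside features averaged 24.0% in ADF+ENZ and 25.9% in ENZ, and reads not aligned 12.6% and 9.93%. Ambiguous reads (3.62% and 4.47%) and the scaling factor (0.953 and 1.02) did not overlap between the groups (exact two-sided permutation p = 0.0286 for each, not passing after adjustment). Camera with its preset correlation called 10 of 39 lists in this comparison and fry called 0, so each list call here rests on that preset. Glucocorticoid-induced genes were higher. Zbtb16 rose from 15.2 ± 6.05 to 61.7 ± 21.5 CPM (SD, n = 4; log2 2.03, SE 0.389, edgeR adjusted p = 0.0306), Fkbp5 by 1.06 and Klf9, a steroid-responsive transcription factor gene, from 141.1 ± 36.2 to 246.0 ± 20.7 CPM (log2 0.80, SE 0.174, 0.0374). Of 19 members 4 rose and none fell, 11 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.1e-06; adjusted p = 0.539 with an estimated correlation). Cpt1a rose from 201.5 ± 29.5 to 324.1 ± 38.2 CPM (log2 0.69, SE 0.118, edgeR adjusted p = 0.0107); in its list, 1 of 20 members rose and 5 adjusted over the list alone (camera adjusted p = 0.00120; adjusted p = 0.539 with an estimated correlation).

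FOXO-induced genes had 3 of 22 up in ADF+ENZ against ENZ, 5 adjusted over the list alone. These were Fbxo32 (log2 0.75), a ubiquitin ligase gene known from fasting muscle, Bcl6 (0.63) and the death-promoting Bcl2l11 (0.44) (camera adjusted p = 0.00120; adjusted p = 0.539 with an estimated correlation). Androgen response genes had 3 of 90 up and none down, Fkbp5, Herc3 (0.77) and Mertk (0.71); adjusted over the list alone 16 rose and 1 fell (camera adjusted p = 0.00624; adjusted p = 0.539 with an estimated correlation; 0.0788 by camera without ENZ replicate 1). Extracellular matrix genes Fn1 (0.89) and Vcan (0.88) rose. Among genes that fell were the inflammatory cytokine gene Il1b, from 9.47 ± 2.10 to 2.19 ± 0.893 CPM (log2 -2.04, SE 0.358, edgeR adjusted p = 0.0179), the linker histone gene Hist1h1a (-1.44, SE 0.195, 0.00315) and Hexa (-0.52, SE 0.0861, 0.00872). Bcl6b (-1.12), Icam2 (-1.10) and Tal1 (-0.93) fell as well, and each lost its call in at least 3 of the 8 fits with 1 library left out. In the 14-gene endothelium list none passed over all genes and 1 fell adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.0151; adjusted p = 0.900 with an estimated correlation; lost without ENZ replicate 2 or ADF+ENZ replicate 3). Glycolysis and hypoxia genes, lower in the 3 comparisons with Vehicle, had none of 31 past the threshold here in edgeR, with 1 by DESeq2 and none by limma-voom, and a median of -0.10 (camera adjusted p = 0.0610).

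In total 206 of 18946 genes changed, 154 up and 52 down, with 23 by more than 2-fold. CPM ranges did not overlap for 1642 genes, 8.67%, against 2.86% by chance, and for 197 of the changed genes. The count rested on single libraries: it was 111, 120, 36 and 41 without ENZ replicates 1, 2, 3 and 4, and 45, 358 and 20 without ADF+ENZ replicates 1, 2 and 3. Of the 35 named genes that passed, Hist1h1a and Hexa kept their call in every such fit and 32 lost it without ADF+ENZ replicate 3; the count was 54 with only these 2 groups in the fit, 668 by DESeq2, 113 (70 up and 43 down) with trends on GC content and length removed, and 43 with reads outside features as a covariate.

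ADF+ENZ against ADF asks what enzalutamide changed in fasted mice, and its 2 groups differ in library make-up (24.0% and 32.9% of reads outside features). Genes of protein synthesis and mitochondrial respiration were higher in ADF+ENZ. Of 76 cytosolic ribosomal protein genes 35 rose and none fell, 55 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 1.34e-15; adjusted p = 0.551 with an estimated correlation). Examples are Rpl15 (log2 0.57), Rpl17 (0.52) and Rps25 (0.48), whose reads can be shared with processed pseudogenes. Of 60 nuclear-encoded oxidative phosphorylation genes 29 rose, 40 adjusted over the list alone (camera adjusted p = 1.79e-14; adjusted p = 0.499 with an estimated correlation). Ndufs8 of complex I rose from 26.02 ± 2.16 to 39.9 ± 5.88 CPM (SD, n = 4; log2 0.61, SE 0.105, edgeR adjusted p = 0.00262) and Sdhb of complex II by 0.53. Of 15 mitochondrially encoded transcripts 11 rose, 14 adjusted over the list alone (camera adjusted p = 3.27e-08; adjusted p = 0.499 with an estimated correlation), such as mt-Co1 from 6599 ± 345 to 9795 ± 1400 CPM (log2 0.57, SE 0.117, edgeR adjusted p = 0.00551).

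Translation factors had 15 of 42 up in the same comparison, 21 adjusted over the list alone, with Eif3h at 0.52 (camera adjusted p = 3e-08; adjusted p = 0.551 with an estimated correlation). MYC-induced ribosome biogenesis genes had 13 of 48 up, 21 adjusted over the list alone, with Pes1 at 0.63 and Nip7 at 0.51 (camera adjusted p = 3.76e-07; adjusted p = 0.599 with an estimated correlation). ER chaperone genes had 6 of 24 up, 11 adjusted over the list alone, with Canx at 0.47 (camera adjusted p = 0.00155; adjusted p = 0.599 with an estimated correlation). Androgen response genes had 15 of 90 up and 4 down, 23 and 4 adjusted over the list alone, with Lman1 at 0.51 and Scd1 at 0.59 (camera adjusted p = 0.00977; adjusted p = 0.499 with an estimated correlation). Interferon response genes had 8 of 38 down, 12 adjusted over the list alone, with Oas2 at -1.35 (SE 0.206, edgeR adjusted p = 0.00142), Irf7 at -0.71 and Trim30a at -0.63 (camera adjusted p = 0.000783; adjusted p = 0.812 with an estimated correlation). Autophagy and lysosome genes had 4 of 32 up, also 4 adjusted over the list alone, with the protease gene Ctsl at 0.78 (camera adjusted p = 0.00627; adjusted p = 0.551 with an estimated correlation). Hsd11b1, whose enzyme regenerates active glucocorticoid, rose from 9.35 ± 3.71 to 28.3 ± 7.53 CPM (log2 1.60, SE 0.355, edgeR adjusted p = 0.0114). Apod, the apolipoprotein D gene, fell from 18.7 ± 4.74 to 3.26 ± 0.738 CPM (log2 -2.48, SE 0.446, edgeR adjusted p = 0.00478), and the proteoglycan gene Omd by 2.39. Small RNA genes Snord118 (1.92), Rny3 (1.85) and Rnu12 (1.55) rose; reads of such short transcripts depend on the library preparation.

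In total 3081 of 18946 genes changed between ADF+ENZ and ADF, 1652 up and 1429 down, with 607 by more than 2-fold. Protein-coding genes had 1455 up and 740 down, long noncoding genes 31 up and 251 down, and the provisional TEC class 8 up and 337 down. CPM ranges did not overlap for 3889 genes, 20.5%, against 2.86% by chance, and for 2479 of the changed genes. The count was 1627 and 1197 without ADF replicates 3 and 4, and 1931 and 1274 without ADF+ENZ replicates 1 and 3, and 54 of the 90 named genes that passed kept their call with any 1 library left out. With reads outside features as a covariate edgeR called 0 genes. Without the covariate DESeq2 called 3710 and limma-voom 4444, and 6226 genes had an unadjusted edgeR p under 0.05. With protein-coding genes alone edgeR called 1917.

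Camera also called lists with few changed members. In ENZ against Vehicle the FOXO-induced list had 1 of 22 up and 3 down (adjusted p = 0.0118; adjusted p = 0.569 with an estimated correlation; 0.0678 by camera without Vehicle replicate 3), and the 15 mitochondrially encoded transcripts 1 up (adjusted p = 0.00213; adjusted p = 0.569 with an estimated correlation). In ADF+ENZ against ENZ the S phase list was lower with no member past the edgeR threshold and a median of -0.17 (adjusted p = 0.00252; adjusted p = 0.900 with an estimated correlation; lost without ENZ replicate 3). In ENZ against Vehicle camera called G2/M genes higher with 0 of 39 members past the edgeR threshold (adjusted p = 0.0379; adjusted p = 0.727 with an estimated correlation), a call lost without Vehicle replicates 3 or 4 or ENZ replicates 3 or 4. No member of the fatty acid synthesis list passed there, and 2 of 16 circadian clock genes fell. Over the 8 contrasts camera with its preset correlation made 108 calls, fry made 47 and camera with an estimated correlation made none, with a smallest adjusted p = 0.191. Of the 108 calls 68 held in every fit with 1 library left out, and 97 with GC and length trends removed.

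**Figure D3:**
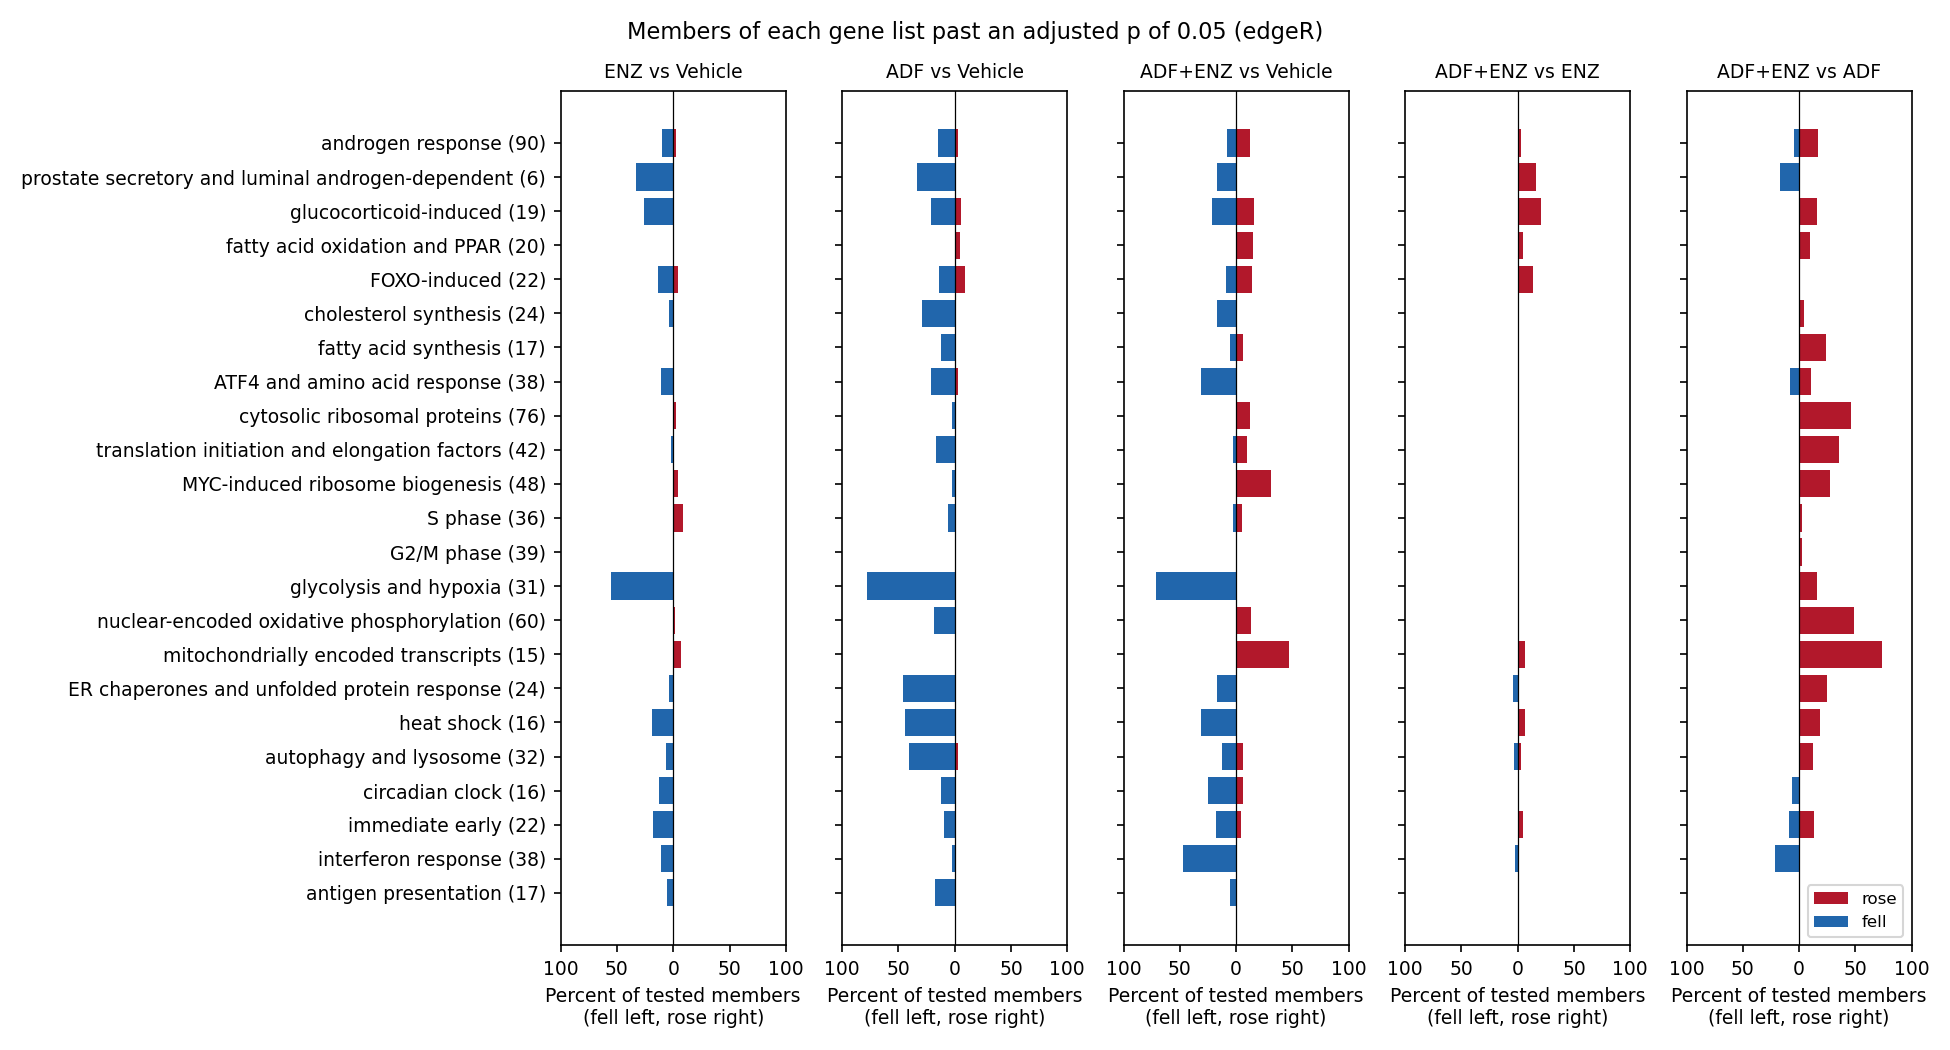
Percent of the tested members of each gene list that rose (right) or fell (left) at an edgeR adjusted p under 0.05 in the 5 pairwise comparisons. Glycolysis and hypoxia genes fell in the 3 comparisons with Vehicle, 17, 24 and 22 of 31, and ribosomal protein genes rose in ADF+ENZ against ADF, 35 of 76.

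The 2-by-2 design gives 3 further contrasts. The average effect of fasting over both drug states covered 958 genes, 447 up and 511 down. Glycolysis and hypoxia genes had 22 of 31 down in it, 25 adjusted over the list alone (camera adjusted p = 1.19e-20; adjusted p = 0.416 with an estimated correlation), and cholesterol synthesis genes 4 of 24 down, with 15 down and 1 up adjusted over the list alone (camera adjusted p = 6.84e-06; adjusted p = 0.786 with an estimated correlation). In ADF against Vehicle 24 and 7 members of these lists fell, and in ADF+ENZ against ENZ 0 and 0. Such counts are no test of a difference, and the first comparison uses the ADF libraries. Cholesterol synthesis was called in the interaction with 0 members past the threshold (camera adjusted p = 0.000198; adjusted p = 0.564 with an estimated correlation). The average effect of enzalutamide over both diets covered 3278 genes, 1695 up and 1583 down. Cytosolic ribosomal protein genes had 33 of 76 up in it, nuclear-encoded oxidative phosphorylation 26 of 60 up, MYC-induced ribosome biogenesis 24 of 48 up, mitochondrially encoded transcripts 12 of 15 up, S phase 10 of 36 up and the interferon response 14 of 38 down. Camera called these 6 lists, with adjusted p from 4.26e-13 to 4.47e-06, and with an estimated correlation none (adjusted p from 0.569 to 0.777). For 3 of them the average covers unlike counts: 2 of 76 ribosomal protein genes, 1 of 60 oxidative phosphorylation genes and 1 of 15 mitochondrially encoded transcripts rose in ENZ against Vehicle, against 35, 29 and 11 in ADF+ENZ against ADF, which uses the ADF libraries. Camera called these 3 lists in the interaction (adjusted p = 4.57e-07, 5.4e-07 and 0.0046; adjusted p = 0.668, 0.550 and 0.644 with an estimated correlation), also in each of the 16 fits with 1 library left out, with 0 members past the edgeR threshold. In ENZ against Vehicle camera also called ribosomal protein and oxidative phosphorylation genes upward, in 7 and 6 of the 8 fits with 1 library left out. Those calls were lost with GC and length trends removed (camera adjusted p = 0.0734 and 0.140). In ADF+ENZ against Vehicle both lists were called upward, each in 7 of 8 such fits. They were also called there with GC and length trends removed (camera adjusted p = 0.00115 and 0.0145). Without ENZ replicate 3 the counts of genes for fasting and enzalutamide were 567 and 2069. The fasting count was also 624 without Vehicle replicate 3, 630 without ENZ replicate 4 and 633 without ADF replicate 4, 1560 by DESeq2, and 542 with reads outside features as a covariate (58.5% up in place of 46.7%). The enzalutamide count was 2100 without ADF replicate 4, 1932 with muscle markers as a covariate and 27 with reads outside features as covariate.

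The interaction tests whether fasting acted differently with and without enzalutamide, and 587 genes passed, 413 positive and 174 negative. The 5 genes with the smallest p had lower means in both single-treatment groups, and also in ADF+ENZ, than in Vehicle. Ly6a, a surface antigen gene, was at 472.8 CPM in Vehicle, 194.5 in ENZ, 277.0 in ADF and 271.3 in ADF+ENZ (interaction 1.25, SE 0.137, edgeR adjusted p = 0.000403). Nfil3, a clock-related repressor gene, was at 33.6, 13.8, 14.6 and 18.8 CPM in the same order (1.65, SE 0.2001, edgeR adjusted p = 0.000837), the sulfite oxidase gene Suox at 81.8, 28.7, 37.8 and 33.8, the metallothionein gene Mt1 at 154.1, 90.3, 78.1 and 103.9, and Arl4a at 91.0, 50.1, 57.3 and 62.8. Their interactions were 1.35, 1.18 and 0.996 for Suox, Mt1 and Arl4a, and all 5 and Fkbp5 passed with any 1 library left out. Of 31 glycolysis and hypoxia genes 16 had a positive interaction, 22 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 3.7e-14; adjusted p = 0.272 with an estimated correlation). This list differed less between the treated groups, with medians of -0.10 in ADF+ENZ against ENZ and 0.17 in ADF+ENZ against ADF. The interaction uses the Vehicle libraries, so high levels in them cannot be told apart here from treatments that act differently together. Glucocorticoid-induced genes had 4 of 19 positive, 6 adjusted over the list alone, with a median of 0.96 (camera adjusted p = 2.42e-08; adjusted p = 0.272 with an estimated correlation). Androgen response genes had 11 of 90 positive, 18 adjusted over the list alone (camera adjusted p = 4.2e-05; adjusted p = 0.266 with an estimated correlation), and autophagy and lysosome genes 5 of 32, 13 adjusted over the list alone (camera adjusted p = 5.32e-07; adjusted p = 0.266 with an estimated correlation). The count of genes was 224 and 190 without Vehicle replicates 2 and 3, 325, 357 and 391 without ENZ replicates 2, 3 and 4, 309, 294 and 148 without ADF replicates 2, 3 and 4, and 209, 908 and 175 without ADF+ENZ replicates 1, 2 and 3. It was 350 with protein-coding genes alone and 0 in edgeR with reads outside features as a covariate. Without the covariate it was 1377 by DESeq2 and 870 by limma-voom, and 4027 genes had an unadjusted edgeR p under 0.05.

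Fold changes of the 2 fasting contrasts that share no tumour, ADF against Vehicle and ADF+ENZ against ENZ, had a Pearson correlation of 0.0342 and a Spearman correlation of 0.0061 across 18946 genes, which are not independent replicates. The Pearson correlation was 0.101 over 9824 genes with a mean of at least 10 CPM and 0.0906 over protein-coding genes. Of the genes called in both, 18 rose in both and 12 fell in both, against 6.23 and 2.58 from independent calls, and 7 moved in opposite directions. Of 99 random regroupings of the 16 libraries 37 gave a Pearson correlation at or above the observed one. For enzalutamide, ENZ against Vehicle and ADF+ENZ against ADF, the correlations were 0.262 and 0.225, with a Pearson correlation of 0.370 over the 9824 genes and 0.310 over protein-coding genes. Here 108 genes rose in both and 124 fell in both, against 29.8 and 51.7 from independent calls, with 25 in opposite directions, and 5 of 99 random regroupings lay at or above. Random regroupings ranged from -0.456 to 0.415.

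**Figure D4:**
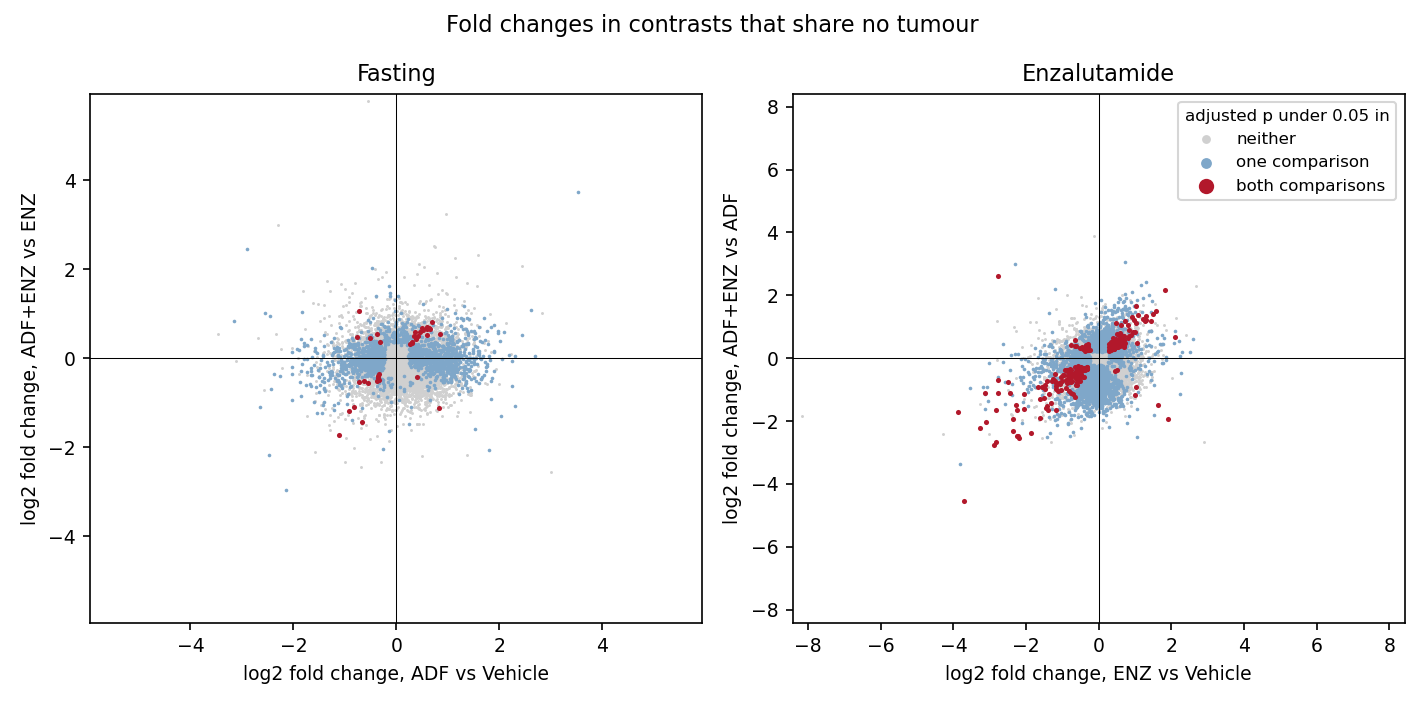
Log2 fold change of each of 18946 genes in a pair of contrasts that share no tumour, for fasting (left) and enzalutamide (right), with colour for the number of contrasts that called the gene. The cloud has no visible slope for fasting (Pearson 0.0342 over these genes) and a shallow positive one for enzalutamide (0.262).

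Marker lists of 16 other or specific cell types were compared as mean log2 CPM. Of 80 exact two-sided permutation tests 5 gave p = 0.0286, the smallest possible, and 0 passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.229). Basal epithelium was involved in 4 of them: its mean level was -0.31 in ENZ, 0.22 in ADF and -0.55 in ADF+ENZ relative to Vehicle, and -0.77 in ADF+ENZ relative to ADF. The fifth was neuroendocrine in ADF+ENZ against Vehicle, at -0.53. Camera called basal epithelium in ADF+ENZ against ADF, with 2 of 5 members down, 3 adjusted over the list alone, among them the basal transcription factor gene Trp63 (-1.75) and the integrin gene Itgb4 (-0.44) (adjusted p = 0.0294; adjusted p = 0.499 with an estimated correlation), a call lost without ADF replicate 1 or ADF+ENZ replicate 1. It called luminal epithelium downward in ENZ against Vehicle (adjusted p = 0.0439; adjusted p = 0.569 with an estimated correlation) and in ADF+ENZ against Vehicle (adjusted p = 0.0203; adjusted p = 0.730 with an estimated correlation), where Krt19 alone of 9 members passed. The first of these calls held in 3 of the 8 fits with 1 library left out and was lost with GC and length trends removed, and the second held in 6 of 8. Fibroblast markers had 1 of 16 up in ADF+ENZ against ENZ, Pdgfra (0.72), and 2 adjusted over the list alone (camera adjusted p = 0.0303; adjusted p = 0.900 with an estimated correlation), a call that held in 4 of the 8 fits with 1 library left out. No marker list of the other types was called by camera in the 5 pairwise comparisons: these were macrophages, T and NK cells, B and plasma cells, neutrophils, dendritic cells, pericytes, adipocytes, skeletal muscle, epidermis, red blood cells, neuroendocrine cells and mesenchymal transition. Some of these lists had few tested members: 2 for epidermis, 5 each for B and plasma, red blood and neuroendocrine cells, and 6 each for neutrophils and adipocytes. For such lists the lack of a call says little. Several lists came close. In ENZ against Vehicle T and NK cells (median -0.72, camera adjusted p = 0.0673) and skeletal muscle (-0.64, 0.0555) were lower and endothelium was higher (0.29, 0.0630), and each was called in 4 of the 8 fits with 1 library left out. In ADF+ENZ against Vehicle macrophages and adipocytes were lower (medians -0.23 and -0.81, camera adjusted p = 0.0712 for both), called in 4 and 2 of 8 such fits. Of the 18 macrophage genes 1 rose and 2 fell in ENZ against Vehicle, Apoe (0.53), Cd68 (-0.48) and Arg1 (-1.52). In ADF 2 fell, Cd68 (-0.44) and Arg1 (-1.40), and in ADF+ENZ Apoe rose (0.73) while Adgre1 (-0.62), Msr1 (-0.64) and Fcgr1 (-0.43) fell.

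Genes in a block around Mdm2, a region singled out after its values were seen, had high transcript levels in all tumours. Over the 16 libraries Cct2, a chaperonin subunit gene, had a mean of 12370 ± 2084 CPM (SD, n = 16), Cpsf6 5547 ± 952, Frs2 5295 ± 751, Mdm2, the gene of the p53 ubiquitin ligase, 5083 ± 671, Slc35e3 3191 ± 702, Yeats4 1005 ± 194 and Rab3ip 699.1 ± 59.4. Genes between them could be far lower, such as Best3 (9.32 ± 3.68 CPM) and Cpm (46.6 ± 11.5 CPM), and Cnot2 and Nup107 outside the block were at 67.8 ± 4.23 and 53.4 ± 5.48 CPM. Lyz2, a lysozyme gene of macrophages that lies in the block, was at 985.3 ± 178 CPM. Against Vehicle, Yeats4 rose in ENZ (0.58), Lrrc10 in ADF (1.11), and Yeats4 (0.58), Slc35e3 (0.55), Cct2 (0.47) and Lrrc10 (0.89) in ADF+ENZ.

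**Figure D5:**
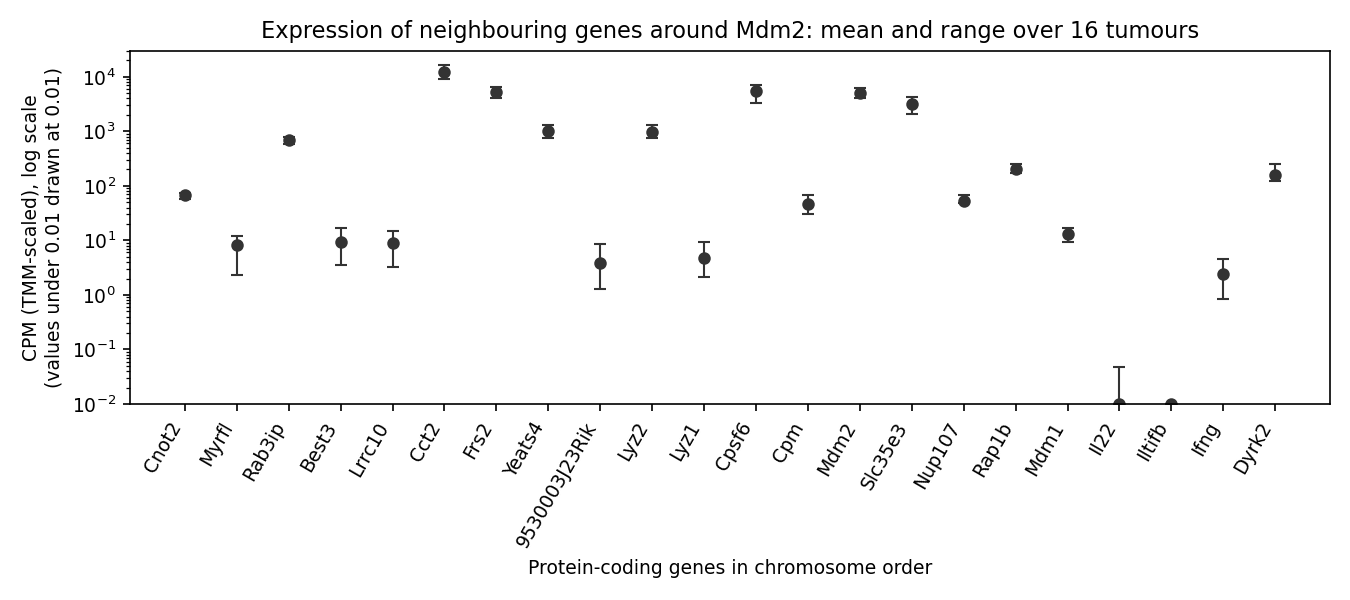
Mean CPM over 16 libraries, on a log axis, of protein-coding genes in their chromosomal order around Mdm2, with bars from the lowest to the highest library. Cct2 (12370), Cpsf6 (5547), Frs2 (5295) and Mdm2 (5083) stand far above the flanking Cnot2 (67.8) and Nup107 (53.4).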

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

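Chosen only after the result was seen were the tests of fasting with or without enzalutamide, a library batch, high Vehicle libraries, a single Vehicle library in ENZ and ADF+ENZ, the make-up of the ADF libraries and a glucocorticoid-type response; the others were chosen before.

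The ADF libraries stood apart in reads that the gene comparisons do not use. Reads in no annotated feature averaged 32.9% in ADF, above the 4 Vehicle libraries (23.4% to 27.9%). Reads not aligned averaged 10.7% in ADF and 12.6% in ADF+ENZ, with Vehicle at 7.47% to 9.10%. A rise in reads outside features was not seen with fasting under enzalutamide, where ADF+ENZ minus ENZ was -1.95 points (exact two-sided permutation p = 0.2). An effect of fasting without the drug stays open, since this difference does not cover it. More unspliced or intergenic RNA in the ADF libraries may contribute, as Spearman's rho of the fold change with gene span over protein-coding genes was 0.149 in ADF against Vehicle and -0.139 in ENZ against Vehicle. With transcript length it was 0.182 in ADF against Vehicle, so a trend with length cannot be told apart from one with span. In ADF+ENZ against ENZ, which uses no ADF library, rho was also positive, 0.0973 with span and 0.137 with length. A library batch stays open: 0 libraries of other groups lay at or below the highest ADF percent of reads aligned to several places, no batch is named in the sources used here, and batch and group cannot be told apart.

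Glycolysis and hypoxia genes were lower than in Vehicle in all 3 other groups. A trend with gene span and expression is argued against, because the list's median in ADF against Vehicle was at percentile 0 of 10000 matched random lists, whose lowest median was -0.26. A single Vehicle library as the whole source is argued against in all 3. In ADF at least 22 members fell whichever one was left out. In ENZ and ADF+ENZ the mean log2 CPM of the list was lower by 0.595 (SE 0.167) and 0.755 (SE 0.152) with all libraries. Without Vehicle replicate 3, which left the smallest differences, these were -0.477 (SE 0.143) and -0.637 (SE 0.126), with no overlap between groups. In ENZ 17 members passed with all libraries, and 7 without Vehicle replicate 3 or without ENZ replicate 3. With the covariate for reads outside features, which nearly coincides with the ADF group, 0 members passed in ADF against Vehicle at a median of -0.69 in place of -0.99, so the make-up of those libraries stays open there. High levels shared by the Vehicle libraries, for a technical or biological reason, cannot be told apart from an effect of each treatment: the median in ADF+ENZ against ENZ, which uses no Vehicle library, was -0.10. That median lay at percentile 0.01 of the matched random lists, whose 5th percentile was -0.023, but camera did not call the list there. It concerns fasting under enzalutamide only. In ADF+ENZ against ADF, which also uses no Vehicle library, the median was 0.17, at percentile 82.85 of the matched random lists. Camera called the list upward there, a call that held in 3 of the 8 fits with 1 library left out. It was lost with GC and length trends removed (camera adjusted p = 0.0859). No fall with enzalutamide was thus seen in fasted mice, though that comparison uses the ADF libraries. An effect of both treatments on glucose use stays open as a hypothesis, untested.

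Fkbp5 was low with either treatment and near Vehicle with both, and the interaction of 1.79 tests that difference. ADF+ENZ replicate 3 as the source is argued against by the value without it, 1.64. The difference between ADF+ENZ and ENZ, 1.06 (SE 0.201), compares no ADF library by design, so it is no test of the make-up of those libraries. That call ended with the covariate for reads outside features (0.94, SE 0.209, edgeR adjusted p = 0.0807). Without the covariate, adjusted p ran from 2.32e-05 by DESeq2 to 0.107 in edgeR without ADF+ENZ replicate 3. For the fall in ADF and for the interaction the make-up stays open. With the covariate the fall went from -0.73 (SE 0.1995) to -0.37 (SE 0.312, edgeR adjusted p = 0.742). DESeq2, fitted without the covariate, gave an adjusted p = 0.00291 for it. The interaction went from 1.79 (SE 0.283) to 1.32 (SE 0.424, edgeR adjusted p = 0.874), while DESeq2 without the covariate gave an adjusted p = 8.89e-08. The edgeR calls ended with a smaller change and a wider spread, as the covariate nearly coincides with the ADF group. In ADF+ENZ against ENZ the other glucocorticoid-induced genes had a median of 0.68, so a glucocorticoid-type response to fasting under enzalutamide may be at work. Fry did not call the list in that comparison. Corticosterone was not measured, androgen and glucocorticoid targets overlap, and the hypothesis was found and tested on the same data.

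A test of the difference between the fasting effects with and without enzalutamide passed for 587 genes, among them Ly6a (1.25), Nfil3 (1.65), Suox (1.35), Mt1 (1.18), Arl4a (0.996) and Fkbp5 (1.79).

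Other splits of the libraries gave fewer genes for 7 contrasts. Only the real one of 35 splits, 1, reached the count in ENZ against Vehicle (1028, highest other 9), ADF against Vehicle (1707, highest other 1), ADF+ENZ against Vehicle (2369, 1), ADF+ENZ against ENZ (206, 1) and ADF+ENZ against ADF (3081, 17). Of 100 drawn splits only the real one reached 958 for average fasting (highest other 342) and 3278 for average enzalutamide (875). For each of these contrasts under 0.05 of the splits, the real one included, reached the count. Other splits mix tumours of the real groups, which raises the spread within a group, so chance is not excluded by them. Nor can they tell a treatment from the make-up of the libraries. For the interaction 2 of 100 splits reached the count, the real one at 587 and another at 750, and what set that split apart was not examined.

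Single libraries far from the rest of their group were found in 39 of 528 tested groups, where chance gives about 1 in 20, 26.4. Ambiguous reads were 5.26% in ENZ replicate 2 (others up to 4.29%), and reads not aligned were 16.7% in ADF+ENZ replicate 3 (others up to 11.4%). In Vehicle, Fkbp5 was 306.2 CPM in replicate 1 (others from 422.4). Replicate 3 had Serpina3m at 76.2 CPM (others up to 41.4) and Vcan at 884.2 (others from 1127), and replicate 4 had Cldn10 at 13.2 (others up to 5.69) and Muc2 at 13.1 (others up to 2.68). ENZ replicate 1 had Jade2 at 98.9 CPM (others up to 83.6), Kcne3 at 8.50 (6.06), Prr15 at 1.70 (0.361), Rny3 at 216.3 (106.7) and Psapl1 at 1.88 (others from 2.46). ADF replicate 1 had Apoc4 at 2.64 CPM (others up to 0.533) and Icam2 at 2.80 (others from 3.80). ADF replicate 2 had Exoc3l4 at 5.33 (others up to 3.76), replicate 3 had Ppp1r9a at 3.46 (others from 4.59) and Siglec15 at 1.34 (others up to 0.645), and replicate 4 had Adgrg2 at 48.3 (others up to 33.2) and Lcn2 at 1.94 (others from 3.997). ADF+ENZ replicate 1 had Mgarp at 1.31 CPM (others up to 0.889), replicate 2 Lamc3 at 5.64 (2.29) and replicate 4 Slc7a2 at 17.8 (10.2). ADF+ENZ replicate 3 had Chrnd at 5.70 (others up to 1.23), Rny1 at 281.9 (89.5), Vcan at 1958 (1395) and Exoc3l4 at 1.53 (others from 2.30).

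Mean log2 CPM of whole lists stood apart in further libraries. In ADF+ENZ replicate 4 these were glucocorticoid-induced genes at 5.12 (others from 5.44), ER chaperones at 6.63 (from 6.68), immediate early genes at 4.79 (from 4.97) and B and plasma cell markers at 1.41 (up to 0.07). In ADF+ENZ replicate 3 they were translation factors at 7.85 (up to 7.73) and MYC-induced ribosome biogenesis at 5.77 (up to 5.64), and in ADF+ENZ replicate 1 the interferon response at 4.18 (up to 3.89). Immediate early genes were at 5.03 in Vehicle replicate 4 (from 5.18), heat shock at 6.63 and mesenchymal transition at 6.00 in ENZ replicate 2 (up to 6.44 and 5.80), and epidermis markers at 1.91 in ENZ replicate 1 (up to 1.47). Cholesterol synthesis was at 3.55 in ADF replicate 2 (from 3.61), and dendritic cell markers at 0.95 in ADF replicate 1 (from 2.06).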

How the results depend on the processing

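Protein-coding genes alone, removal of GC and length trends and the covariate for reads in no feature were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each title has its own number and the groups share none. Where a count moved by more than 1.5 times, the cause was not tested.

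Counts stayed within 1.5 times of the reported one in all 8 contrasts with DESeq2 size factors in edgeR, no filter and the stricter filter. DESeq2 gave more genes in ENZ against Vehicle (1577), ADF+ENZ against ENZ (668), average fasting (1560) and the interaction (1377), and limma-voom gave 1655 in ENZ against Vehicle. The skeletal muscle covariate left 1932 genes for average enzalutamide, and fitting only the 2 groups left 54 in ADF+ENZ against ENZ, with fewer samples to estimate the spread. With protein-coding genes alone ADF against Vehicle had 1119, ADF+ENZ against ADF 1917 and the interaction 350, with fewer genes tested. Removal of GC and length trends left 113 in ADF+ENZ against ENZ, with 62.0% up in place of 74.8%. The covariate for reads in no feature, which nearly coincides with the ADF group, left 6 genes in ADF against Vehicle, 1579 in ADF+ENZ against Vehicle, 43 in ADF+ENZ against ENZ, 542 for average fasting and 27 for average enzalutamide. In ADF+ENZ against ADF and in the interaction edgeR then called 0. Without the covariate DESeq2 called 3710 and 1377 genes in these, and limma-voom 4444 and 870. Unadjusted edgeR p without it was under 0.05 for 6226 and 4027.

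With each library left out in turn, counts ran from 403 to 1194 in ENZ against Vehicle, 610 to 1862 in ADF against Vehicle, 1202 to 2286 in ADF+ENZ against Vehicle, 20 to 358 in ADF+ENZ against ENZ and 1197 to 3403 in ADF+ENZ against ADF. They ran from 567 to 1120 for average fasting, 2069 to 3886 for average enzalutamide and 148 to 908 for the interaction. The lowest were without ENZ replicate 3, ADF replicate 4, ADF+ENZ replicate 3, ADF+ENZ replicate 3, ADF replicate 4, ENZ replicate 3, ENZ replicate 3 and ADF replicate 4.

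List calls by camera numbered 108 with the preset correlation and 0 with an estimated one, and fry made 47. The main fit had 412 named results, and some settings covered fewer of them. By DESeq2 no call was lost, where a result without an adjusted p was counted as kept. Calls lost numbered 63 with only the 2 groups compared, 54 with no filter, 2 with the stricter filter and 32 with the skeletal muscle covariate. They numbered 30 with GC and length trends removed, 17 with protein-coding genes alone, 14 with limma-voom and 6 with DESeq2 size factors in edgeR. With the covariate for reads in no feature 219 were lost. That covariate changed the sign of 10, all in ADF+ENZ against ADF: Me1 (-0.0033), Atf4 (-0.00017), Phgdh (-0.068), Gars (-0.15), Eif3l (-0.019), Eif4a1 (-0.0080), Mcm7 (-0.12), Pgam1 (-0.10), Ldha (-0.047) and Hspa8 (-0.058). Correlations of independent contrasts ran from 0.0340 to 0.101 for fasting, about 3 times the lowest at a mean of at least 10 CPM, and from 0.262 to 0.370 for enzalutamide. Marker levels with a prior count of 0.5 again gave 0 after Benjamini-Hochberg adjustment of exact permutation p, against 6 before it. The floor of that p left passing hardly possible. In simulated data edgeR recovered 42% of genes planted at 1.5-fold in ENZ against Vehicle and 6% for the interaction, so smaller changes were often not detectable at this depth and number of tumours.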

Other observations

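The block around Mdm2 was singled out because its genes had high levels in every group, among them Cct2, Frs2, Cpsf6, Mdm2 and Slc35e3, while Cpm (46.6 CPM) and Lyz1 (4.72 CPM) inside it were low. What lies behind these levels was not tested, as DNA was not measured. Lyz2, which is used as a macrophage marker, lies in the same block (985.3 CPM), so its level alone is no measure of macrophages.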
